A study of Rattus norvegicus with 6 samples.

How the data were processed

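Total RNA of rat bone marrow stromal cells was measured on 6 one-colour Agilent expression arrays labelled with Cy3. Per the labels, the cells came from tibia marrow and were cultured for 7 days, 3 cultures on a tantalum-modified titanium surface (Ta) and 3 on a simple titanium surface (Ti). The series' design text calls the cultures of each group independent experiments. All 6 arrays lay on 1 slide and were scanned together, so slide and scan could not differ between groups. Positions on the slide were not balanced: the Ta arrays and Ti replicate 1 lay in slide row 1, and Ti replicates 2 and 3 in row 2.

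The deposited values are spot intensities on a linear scale. Per the file headers, Agilent Feature Extraction subtracted the background and detrended each array to give the processed signal, without scaling between arrays. The submitters' processing notes name Agilent Feature Extraction 12.0 and limma, the latter without a version. The deposited value table of the series equalled the processed signal in 100% of the values of every array, so it gave no separate alternative. The files of Ta replicate 2 and Ti replicate 3 hold at most 3 significant digits in 100% of their values, and 93 gene names in each differ from those of Ta replicate 1. Names were therefore taken from the file of Ta replicate 1.

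The log2 processed signal of each array was reduced by the 75th percentile over its 58717 non-control spots, and the mean of the percentiles was added back. Spots flagged as outliers, between 0.58% and 0.84% of an array, were treated as missing, and spots of 1 probe were averaged. Of 45598 probes, 25764 were well above background on at least 3 of the 6 arrays, and 25756 of these had a value on every array. A gene was represented by its brightest probe, which gave 19571 genes, with a probe without a gene name counted as a gene of its own. Gene names came through the probe's accession or symbol in a RefSeq table of the GRCr8 assembly for 31220 probes, and the name in the file was kept otherwise. The same table gave the classes protein coding and lncRNA, and for genes not in it the class came from the array's accession or description. No probe (0) was described as a circRNA and 2 as a microRNA, so the circRNA comparisons planned from the series' title are not reported and all probes entered the gene test. No genome was used.

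Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are Ta minus Ti. SE is the moderated standard error of limma, which draws each gene's variance toward that of all genes, so for the most variable genes it understates their own spread. lncRNA genes were adjusted within their class. The 36 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Array structure was tested with an exact permutation test over the 10 splits of the 6 arrays into 3 and 3, which cannot give a p under 0.1. A probe that was not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background. For named genes well above background on only some arrays of the dimmer group, the difference with the other arrays raised to this floor was added after the data were seen. List medians were the same to 2 decimals with such genes at their bound.

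The rule for named genes was fixed before the data were examined. It takes the 12 largest increases and 12 largest decreases among genes with an adjusted p under 0.05, with every Ta array beyond every Ti array, well above background on all 3 arrays of the higher group and with a symbol that is not a placeholder. It also takes up to 4 members per list with the largest change among those past the test, up to 2 by size for a called list with none, and 10 bone genes whatever their result. Genes named outside the rule are marked where they appear.

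The gene test was tested on simulated data for this comparison, with 19571 genes, the measured means and spreads, and 200 genes changed. It recovered 65% of genes changed by 1 on the log2 scale and 88% of those changed by 2, with 5 false calls among 158. With no change simulated it called 0 genes. The simulated noise was independent between genes, unlike that of real arrays. The number of arrays limits the precision.

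Alternatives were quantile, median and detected-probe scaling, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, the replicate number as a block, eBayes with trend and robust settings, array weights, other rules for genes with several probes, an unadjusted threshold, and leaving out each array in turn. Slide row as a block, which sets the Ta arrays against Ti replicate 1 alone, rounding of every array to 3 digits, and leaving out each array for the lncRNA count and the array structure were added after the data were seen.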

Results

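Gene expression was measured in rat bone marrow stromal cells, the adherent marrow cells that can form bone, cartilage and fat cells, after 7 days on a tantalum-modified titanium surface (Ta, n = 3 arrays) or on a simple titanium surface (Ti, n = 3 arrays). Between 62.7% and 65.9% of the non-control spots of an array were well above background, and the 75th percentile of the processed signal lay between 1848 and 2388. The comparison addresses which transcripts differ between cells grown on the 2 surfaces.

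The Ta and Ti arrays separated along the first principal component of the 19571 tested genes, which held 67.6% of the variance. Ta replicate 1 scored 6.7 and Ti replicate 2 scored -22.9, between the other Ta arrays at 43.6 and 57.7 and the other Ti arrays at -40.6 and -44.5. Ta replicate 1 was on average about as far from the other Ta arrays (root mean square log2 difference 0.437) as from the Ti arrays (0.45). Pearson correlations across genes ran from 0.987 to 0.995 within groups and from 0.97 to 0.992 between them. Arrays of different groups differed by 0.214 more, on this log2 scale, than arrays of the same group, with an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. Without Ti replicate 3 the exact p was 0.2. The scanner software marked the array of Ti replicate 2 for evaluation and the other arrays as in range.

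**Figure D1:**
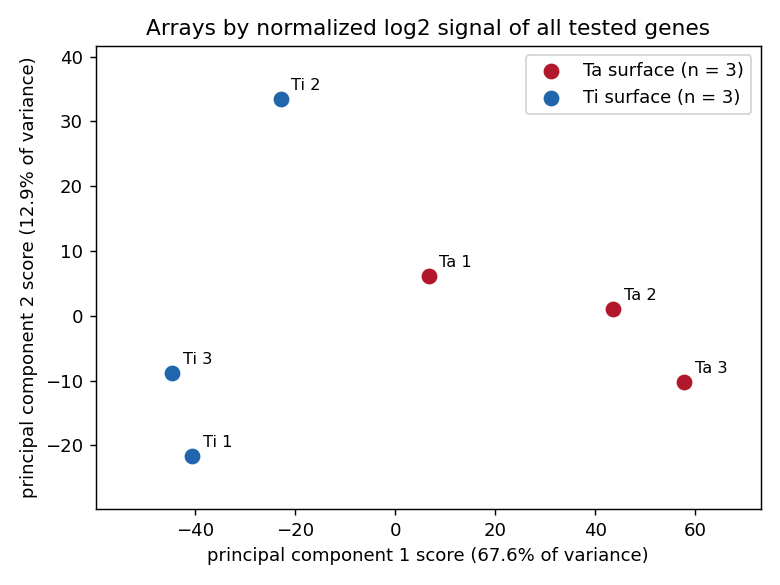
Scores of the 6 arrays on the first principal component (horizontal, 67.6% of variance) and the second (vertical, 12.9%), without units, one point per array, coloured by surface. Ta replicate 1 at 6.7 and Ti replicate 2 at -22.9 are the arrays of each group nearest to the other group.

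Of the 12 largest increases on Ta, 5 were in members of the inflammatory list. Cxcl2 and Cxcl3, chemokines that attract neutrophils, rose by 5.03 ± 0.70 and 3.57 ± 0.47 (log2, SE, n = 3 per group, adjusted p = 0.0397 for both). Csf3 and Csf2, growth factors of granulocytes and macrophages, rose by 3.32 ± 0.62 and 3.18 ± 0.56 (adjusted p = 0.0474 and 0.0452). Csf2 was well above background on 1 of 3 Ti arrays and rose by 2.29 with the others raised to at least the floor, the lowest signal among probes well above background. Nos2, the inducible nitric oxide synthase, was not well above background on any Ti array and was at least 15.5-fold higher on Ta on average. The adjusted p of 0.0397 from limma belongs to the difference without the floor, and the bound itself was not tested. Ta replicate 1 lay at 5.69, and Ta replicates 2 and 3 at 8.6 and 8.25. The chemokine Ccl6 rose by 3.84 ± 0.67, the interleukin 13 receptor gene Il13ra2 by 3.37 ± 0.48, Wfdc21 by 4.32 ± 0.33, Pcp4 by 3.78 ± 0.68 and Dmkn by 3.30 ± 0.52 (well above background on 1 of 3 Ti arrays, 2.95 with the floor), and Serpinb3a was at least 4.23-fold higher. The probe used for Saal1 rose by 3.53 ± 0.52, but a second probe of that gene gave 0.17, so the gene is uncertain.

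Among the 12 largest decreases on Ta, Cd5l, a protein secreted by macrophages, fell by 4.22 on the log2 scale (SE 0.75, adjusted p = 0.0452). The mast cell protease genes Cma1 and Mcpt1l1 were not well above background on any Ta array and were at least 3.49-fold and 4.15-fold lower. Mcpt1l1 belongs to a family of near-identical genes, so its probes are uncertain. The matrix metalloproteinase Mmp7 fell by 3.86, Cpxm2 by 3.83, Tmem176a by 3.82 and Wfdc1 by 3.80 (a second probe of Wfdc1 gave -2.14). Tmem176b fell by 3.46. Mmp7 and Cpxm2 were well above background on 1 of 3 Ta arrays, and Cd5l and Tmem176a on 2 of 3. With the floor, Mmp7 fell by 3.77, Cpxm2 by 3.37, Cd5l by 3.86 and Tmem176a by 3.81. Pld4, Diras2, Fam3b and Fxyd1 were at least 3.68-fold, 3.75-fold, 2.62-fold and 2.93-fold lower.

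In all, 812 of 19571 genes passed an adjusted p of 0.05, 522 higher and 290 lower on Ta, and 350 of them differed by at least 2-fold (213 higher, 137 lower). Of the 812, 650 were protein coding, 43 were lncRNA genes and 119 were in neither class. At an unadjusted p under 0.05 there were 5874 genes, and 952 of these differed by at least 2-fold, with the balance turned (414 higher, 538 lower). Of 197 called genes with another tested probe, 18 had a probe that differed in the opposite direction. In each of the 812 genes every Ta array lay beyond every Ti array, as in 35.9% of all tested genes against 10% by chance. The smallest adjusted p was 0.0263, and the count rested on single arrays: limma called 0 genes without Ta replicate 2, Ta replicate 3, Ti replicate 1 or Ti replicate 3 (3812, 3900, 4467 and 3814 at an unadjusted p under 0.05), 3212 without Ta replicate 1 and 1560 without Ti replicate 2. It also called 0 with no filter on dim probes (5814 unadjusted) and 0 with slide row as a block, a setting chosen after the data were seen that sets the 3 Ta arrays against Ti replicate 1 alone (3830 unadjusted), and with median scaling 416 genes were higher and 362 lower.

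**Figure D2:**
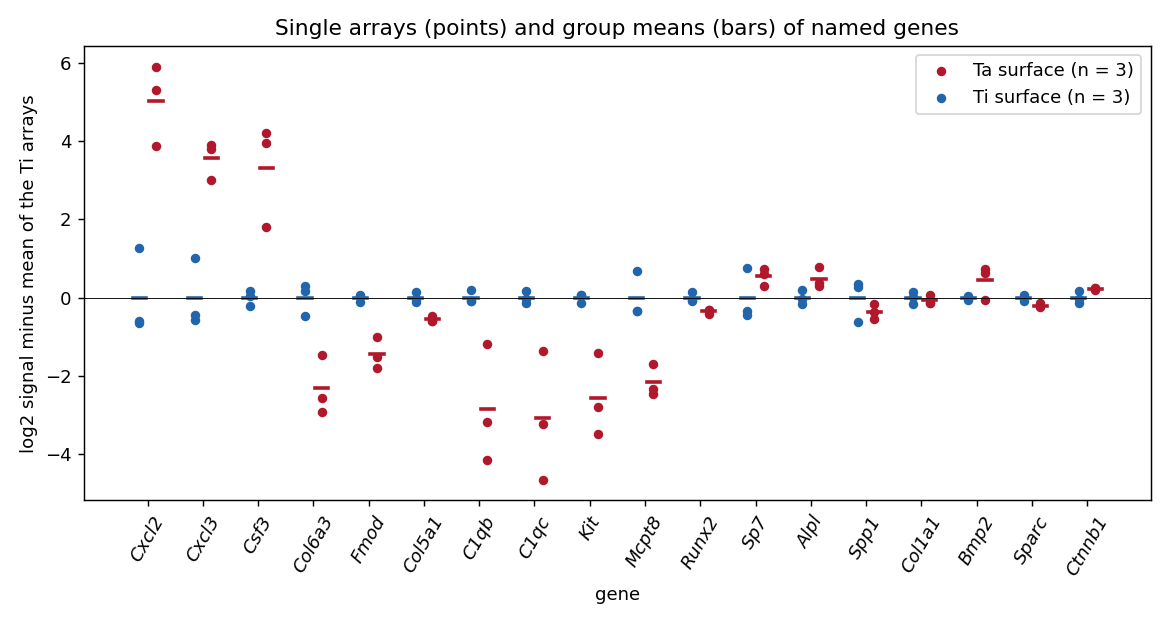
Normalized log2 signal of single arrays (points) and group means (bars) for named genes, each minus the gene's mean over the Ti arrays, with Ta in red and Ti in blue (n = 3 each). Cxcl2, Cxcl3 and Csf3 lie 3.32 to 5.03 higher on Ta on average, and Col1a1 differs by -0.07.

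Of 39 measured genes of inflammatory cytokines and NF-kB signalling, 17 rose, 0 fell and 22 did not pass the test, and 27 rose and 1 fell when adjusted over the list alone. The median log2 difference was 1.12. Besides the genes above, Cxcl6 rose by 3.07 and Il1a by 3.03, and Lcn2 (3.04, adjusted p = 0.0621) did not pass. These 3 are named outside the rule, after their values were seen. The list was higher than other genes by camera (adjusted p = 1.7e-09), with an adjusted p of 0.766 with an estimated correlation and 0.0375 by fry, which tests whether the list moves one way without comparing it with other genes.

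The cell cycle list had a median of 0.56, with 47 of 48 genes above 0. The rise rests on Ta replicates 2 and 3, where the list's mean was 9.91 on each, against 9.32 on Ta replicate 1 and 9.12 to 9.28 on the Ti arrays. Cdca8, a component of the chromosomal passenger complex, rose by 0.98 ± 0.16 and 47 genes did not pass, while 24 rose when adjusted over the list alone. The hypoxia and glycolysis list (35 genes, median 0.27) had 3 genes that rose and 0 that fell, or 8 and 1 when adjusted over the list alone. These were Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factor (1.91 ± 0.35), the glucose transporter Slc2a1 (0.76 ± 0.13) and the glycolytic enzyme Pfkl (0.69 ± 0.10). In the oxidative stress and metallothionein list (37 genes, median 0.22), 4 genes rose and 2 fell, or 12 and 2 when adjusted over the list alone. Sod2, the mitochondrial superoxide dismutase, rose by 1.47 ± 0.19, Mt2A by 1.28 ± 0.24 and Gsta1 by 1.07 ± 0.17, and Mt3 was at least 2.05-fold lower. Camera placed the 3 lists above other genes (adjusted p = 7.2e-09, 0.00943 and 0.0106), with adjusted p of 0.824, 0.766 and 0.824 with an estimated correlation and 0.147, 0.0616 and 0.11 by fry.

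Among 39 genes of matrix collagens and crosslinking, 4 fell and 0 rose, and 14 fell when adjusted over the list alone (median -0.21). Col6a3 fell by 2.32 on the log2 scale (SE 0.40), the collagen-binding proteoglycan Fmod by 1.44 (SE 0.20), Col5a1 by 0.54 and Col5a2 by 0.48. Of 27 osteoblast differentiation genes, 3 fell, 1 rose and 23 did not pass, with 7 lower and 1 higher when adjusted over the list alone (median -0.15). Tnfrsf11b, which encodes osteoprotegerin, fell by 1.73 (SE 0.31), the osteoblast transcription factor Dlx5 by 0.96 (SE 0.15) and Bmp3, a BMP antagonist, by 0.59 (SE 0.10), and Sgms2 rose by 0.78 ± 0.14. Of 12 chondrocyte markers, Sox5 fell by 0.59, and 7 fell and 1 rose when adjusted over the list alone (median -0.48). Camera placed these lists below other genes (adjusted p = 2.9e-05, 0.037 and 0.037), with adjusted p of 0.766, 0.817 and 0.766 with an estimated correlation and 0.0616, 0.147 and 0.11 by fry. The osteoblast call was lost without Ta replicate 1 (adjusted p = 0.0543), Ta replicate 2 (0.0667) or Ti replicate 1 (0.0781), and the chondrocyte call without Ta replicate 1 (0.0719), Ti replicate 1 (0.0673) or Ti replicate 2 (0.0588). With median scaling both calls were lost (0.0579 each), and the chondrocyte call also with normexp background correction (0.218), the stricter filter on dim probes (0.14), trend and robust settings (0.0581) and array weights (0.133).

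None of the 8 measured bone genes named in advance passed the test. The log2 differences were -0.35 ± 0.10 (SE) for Runx2, the master transcription factor of osteoblasts (adjusted p = 0.0791), 0.54 ± 0.33 for Sp7 (0.322), 0.49 ± 0.16 for the alkaline phosphatase gene Alpl (0.109) and 0.44 ± 0.21 for Bmp2 (0.216). Spp1 differed by -0.36 ± 0.27, Sparc by -0.20 ± 0.08, Ctnnb1 by 0.23 ± 0.10 and Col1a1 by -0.07 ± 0.12 (adjusted p = 0.423, 0.165, 0.189 and 0.742). Sp7 was well above background on 1 of 3 Ti arrays. Other probes gave 0.13 for Col1a1, 0.26 and 0.28 for Bmp2, and -0.41 and 0.11 for Ctnnb1. With array weights, which gave Ta replicate 2 a weight of 7.35 and the other arrays 0.32 to 2.74, 6 of the 8 passed: Runx2 (-0.4), Spp1 (-0.78) and Sparc (-0.27) lower, and Alpl (0.41), Bmp2 (0.65) and Ctnnb1 (0.33) higher. With these weights 10160 of all 19571 genes passed, so passing was not particular to bone genes. Without Ta replicate 1, Bmp2 passed (0.69, adjusted p = 0.0132), as did 3212 of all genes. Ibsp and Bglap were well above background on 2 of 6 arrays each and were not tested.

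Markers of other marrow cells were examined beside these groups. Of 25 macrophage and monocyte markers, 0 passed the test over all genes and 6 fell when adjusted over the list alone, with a median of -0.69. The complement genes C1qc and C1qb, made by tissue macrophages, differed by -3.08 ± 0.77 and -2.83 ± 0.71 (adjusted p = 0.07 and 0.0695). Both passed with array weights, with normexp background correction (at smaller differences of -1.77 and -2.71, adjusted p = 0.0196 and 0.0315) and without Ta replicate 1 (0.0098 and 0.00773). These settings called 10160, 2598 and 3212 of all 19571 genes. Camera placed the list below other genes (adjusted p = 4.9e-04), with an adjusted p of 0.824 with an estimated correlation and 0.347 by fry. Of 11 megakaryocyte and mast cell markers, 4 fell and 1 rose, among them Kit, the stem cell factor receptor (-2.56 ± 0.49), and the mast cell genes Mcpt8 (-2.16 ± 0.34) and Cpa3 (-1.93 ± 0.29). Cpa3 was well above background on 1 of 3 Ta arrays (-1.62 with the floor). A second probe of Mcpt8 gave -0.41. This list was not called by camera (adjusted p = 0.0585), and fry gave 0.0298. Of 6 neutrophil markers (median 1.67), S100a8 rose by 2.95 ± 0.50 and Camp by 1.68 ± 0.30 (camera adjusted p = 0.0903, fry 0.00743). When adjusted over the list alone, 4 rose and 0 fell. Among 18 mesenchymal stromal markers, Cxcl12 rose by 1.06 ± 0.19, Kitlg, the ligand of Kit, by 0.67 ± 0.13 and Thy1 by 0.67 ± 0.11, with 15 not past the test and other probes of Cxcl12 at 0.65 to 1.33 and of Thy1 at 0.36 (camera adjusted p = 0.687).

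Camera called 8 of the 36 lists, 4 higher and 4 lower. With an estimated correlation it called 0 (0 at an unadjusted p under 0.05), and fry called 4, of which 1 was among the 8. Another split of the same arrays, Ta replicate 1 with Ti replicates 1 and 2 against the rest, gave 10 calls by camera with the preset correlation. The list of ribosomal protein genes, kept as a quality check, had a median of 0.01 over 47 genes with 0 past the test, and oxidative phosphorylation had 0.01 over 51. The other quality list, immediate early and heat shock genes (31 genes, median -0.05, mean -0.29), had 2 genes that fell and 0 that rose, or 9 and 2 when adjusted over the list alone, and was not called by camera (adjusted p = 0.0884). The Wnt list (41 genes, median 0.03) was not called by camera (adjusted p = 0.756). In it, Rspo3 rose by 1.62 ± 0.18 and Sfrp2 by 1.26 ± 0.17. Wif1 fell by 1.36 (SE 0.10) and the receptor Fzd6 by 0.41 (SE 0.08).

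**Figure D3:**
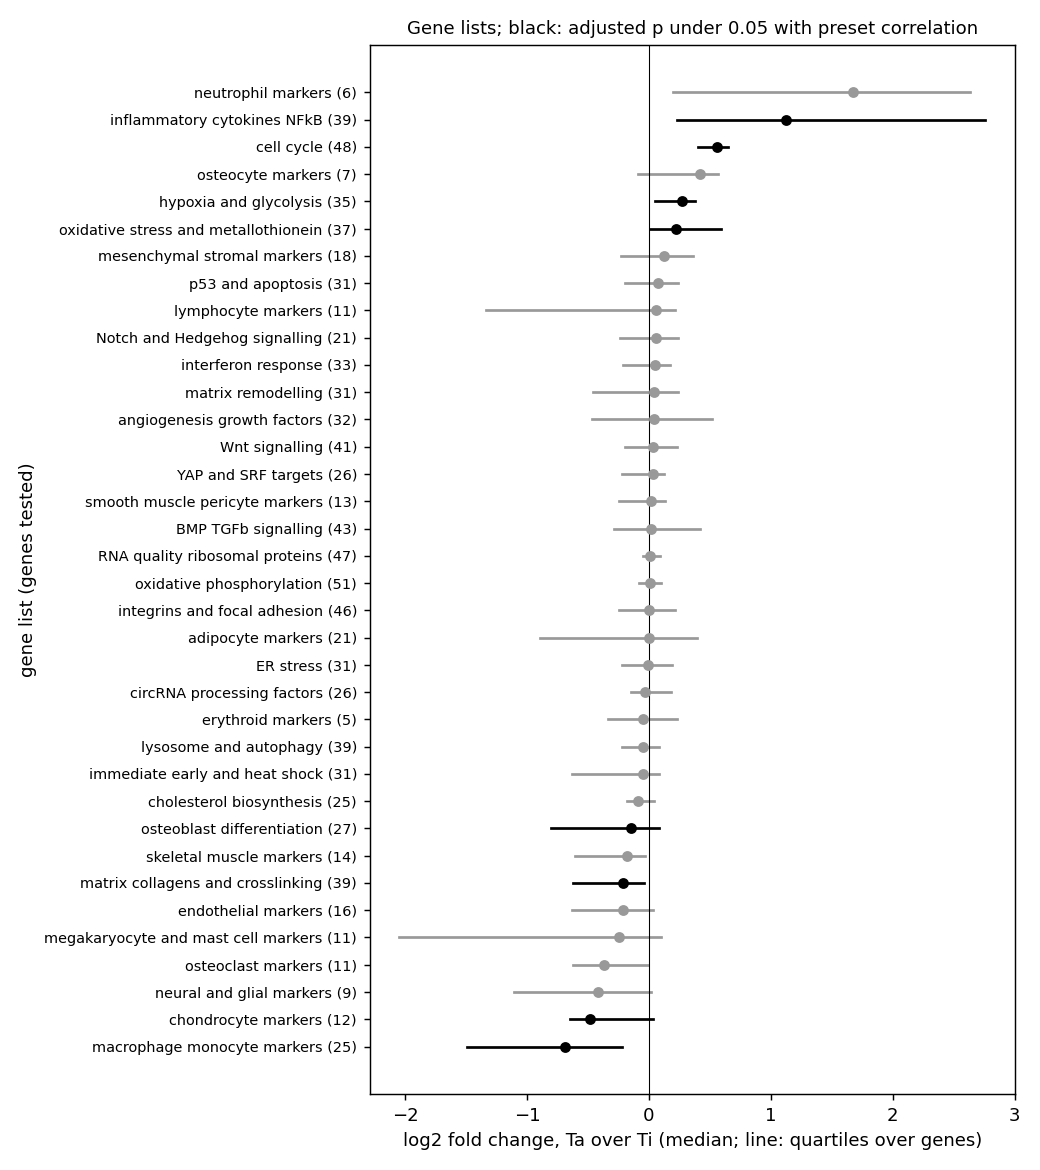
Median log2 fold change, Ta over Ti, of the genes of each list (points) with quartiles over genes (lines), lists on the vertical axis with the number of genes tested, and lists called by camera with the preset correlation in black. The inflammatory list has a median of 1.12 and the macrophage list of -0.69.

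Among long noncoding RNA genes, 28 of 1264 passed an adjusted p of 0.05 within the class, 19 higher and 9 lower on Ta. When adjusted over all genes, 43 passed. The imprinted gene Meg3, named after its value was seen, fell by 2.85 on the log2 scale (SE 0.50, adjusted p = 0.0481 within the class), and a second probe gave -1.29. The count was 0 without Ta replicate 2 (235 at an unadjusted p under 0.05 in limma), 9 without Ta replicate 3, 12 without Ti replicate 1, 4 without Ti replicate 3, 144 without Ta replicate 1 and 53 without Ti replicate 2.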

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

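Slide row as a block, rounding to 3 digits, and leaving out arrays for the lncRNA count and the array structure were chosen after the data were seen. The 812 genes called by limma became 2598 with normexp background correction, 2088 with trend and robust settings, 10160 with array weights, 0 with no filter on dim probes and 0 with slide row as a block, and from 0 to 3212 when each array was left out in turn. In the fit with slide row as a block, Ti replicates 2 and 3, alone in their row, drop out of the difference, and Ti replicate 1 is assumed to vary like the other arrays. The cause of the other changes was not tested. The other scalings, probe rules and filters gave counts within 1.5 times, and the 812 genes all had the same sign with quantile scaling (792 called) and median scaling (778 called). The lncRNA count ranged from 0 to 144 without single arrays. The 8 lists called by camera became 0 with an estimated correlation and were 6 to 9 without single arrays. Fry called 4 lists, 1 of them among the 8. The array distance ranged from 0.161 to 0.314 without single arrays (exact p of 0.2 without Ti replicate 3, 0.1 otherwise).

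The replicate block cut the genes called to 8 and the lncRNA genes to 9. The arrays gave no sign that the numbers pair the samples. Deviations from the group means correlated at 0.06, 0.13 and -0.18 for replicates 1, 2 and 3. Not every array correlated best with its own number (Ta replicate 1 with Ti replicate 3, 0.18). With 3 arrays per group these correlations cannot exclude a pairing. Rounding every array to 3 digits, as in the files of 2 arrays, gave 810 genes.

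Among named genes, none of them called, Col1a1 changed sign without Ti replicate 1 (0.01, with a range from -0.15 to 0.01 over the arrays left out) and with the mean of its probes (0.03), Ctnnb1 with the mean of its probes (-0.02) and Sp7 with slide row as a block (-0.23, against Ti replicate 1 alone). Of the named genes not called, 8 passed with array weights, 6 of them bone genes, 3 without Ta replicate 1 and 2 with normexp. The series' value table and a block for slide or scan were not run, since the first equals the scanner values and there is 1 slide and 1 scan. The circRNA alternatives were not run for lack of such probes. Signal over background limits 65 of the 812 genes, which were not well above background on any array of the lower group.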

Other observations

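Of the tests of explanations below, those on exchanged labels, macrophage number and neutrophils and the split count of genes were chosen after the result was seen. Of 32 angiogenesis and growth factor genes, 5 rose and 2 fell, with a median of 0.04 (camera adjusted p = 0.895). Hgf rose by 1.37 ± 0.27 (log2, SE) and Angpt1 by 1.33 ± 0.25 on Ta, and Igf1 fell by 1.09 (SE 0.15; its 4 other probes gave -1.34 to -0.42). The lipoprotein lipase gene Lpl fell by 2.46 (SE 0.44), and the immediate early genes Fosb and Egr1 fell by 1.16 and 0.98. Of 13 smooth muscle and pericyte markers, Cspg4 fell by 1.87 (SE 0.29) and Kcnj8 rose by 1.13 ± 0.22, with a list median of 0.02 (camera adjusted p = 0.714). Dio3, named after its value was seen, encodes a deiodinase that inactivates thyroid hormone and is imprinted like its chromosomal neighbour Meg3. It fell by 2.74 (SE 0.49). Of the genes from Dlk1 to Dio3 in the reference table, 0 besides Meg3 and Dio3 were tested, so whether the interval changed together was not tested.

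Ta replicate 1 and Ti replicate 2 lie between the other arrays. On 260 genes chosen from the other 4 arrays, with 0 at the other Ti arrays and 1 at the other Ta arrays, Ta replicate 1 lay at 0.49 (95% bootstrap interval 0.46 to 0.53) and Ti replicate 2 at 0.24 (0.22 to 0.26). These intervals resample genes within an array and do not measure how cultures vary. Signal of the other surface mixed into an array would give 1 linear share for all genes. The share differed between genes higher and lower on Ta by 0.29 in Ta replicate 1 and by -0.32 in Ti replicate 2. Choosing genes by their difference between the other 4 arrays pushes the shares in these same directions, by an amount not measured. How far the differences speak against mixing as the whole cause therefore cannot be told. With the labels of both arrays exchanged, Ta replicate 1 would lie nearer to Ti and Ti replicate 2 nearer to Ta. Ti replicate 2 lay nearer to Ti, but the interval of Ta replicate 1 holds the midpoint, and each position rests on 1 array. An exchange therefore stays open, and slide position and differences between cultures were not tested for this pattern.

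The macrophage list was placed below other genes by camera with the preset correlation, but not with an estimated one (adjusted p = 0.824) or by fry (0.347), and 0 of its 25 markers passed the test. The mean over the markers was 10.31 to 11.71 on the Ta arrays and 11.84 to 12.04 on the Ti arrays. Fewer macrophages as the only change would lower the markers by about the same factor and raise none. Of 300 pairs of markers, 169 (56.3%) differed in their change at an unadjusted p under 0.05. The pairs reuse the same 25 markers and are not independent, so how high this share could be under a common factor is not known. Of the 25 markers, 0 rose when adjusted over the list alone, and a marker that stromal cells also express would fall less. The rise of 17 of 39 inflammatory genes argues against fewer macrophages as the only change in the cultures. As the only cause of the lower markers, fewer macrophages stay open, since which markers stromal cells express is not known from these arrays. A change in the state of the macrophages also stays open and was not tested.

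Of 39 inflammatory genes, 17 rose on Ta. The macrophage markers gave no sign of more macrophages in the Ta cultures, with a median of -0.69 and 0 of 25 higher when adjusted over the list alone. A change in the state of the macrophages could also lower the markers, so their number is not settled by this. For neutrophils the markers disagreed. Csf3r, their growth factor receptor, differed by -0.88 ± 0.45 (well above background on 2 of 3 Ta arrays) against 2.95 for S100a8. Of 17 neutrophil markers, 9 were not well above background on any array, S100a9 among them. Of the 6 tested markers, however, 4 rose and 0 fell when adjusted over the list alone. Lcn2, 1 of these 4, is also a member of the inflammatory list. Mmp8, well above background on only 2 of 6 arrays and so not tested, differed in the opposite direction, by -2.13 ± 0.35. Mpo differed by 1.66 ± 0.35 (well above background on 5 of 6 arrays). Csf3r, S100a9, Mmp8 and Mpo are named after their values were seen. The SEs of Csf3r, Mmp8 and Mpo come from a fit in which that of S100a8 was 0.52. Macrophages also express Csf3r, and a probe that stays dim may fail, so neutrophils are neither shown nor excluded. Which cells made the inflammatory transcripts, stromal cells or macrophages, and whether the surface itself is the source was not tested.

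With 10 splits of the 6 arrays, no share can fall under 0.05. The real split gave 812 genes against at most 0 in the others (1 of 10 as large) and 28 lncRNA genes against at most 1 (1 of 10). At an unadjusted p under 0.05 in limma the contrast was less sharp, with 5874 genes in the real split and 114 to 2261 in the others. For the lists called by camera the real split gave 8 against at most 10, and 2 of the 10 splits gave as many.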
